A study of Mus musculus with 120 samples.

How the data were processed

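Single cells from mice were sorted into 384-well capture plates and profiled by 3' single-cell RNA sequencing with barcoded cDNA, pooling and T7 amplification, per the labels' protocols. Each sample is 1 plate, called an amplification batch. The labels give the tissue, the sorted population, the diet and the time on the diet: a normal diet (ND) or MCDD, a diet lacking methionine and choline that serves as a feeding model of steatohepatitis, for 2 weeks, and for 4 or 8 weeks in 1 sort. Reads were split with bcl2fastq 2.15.0.4 and the genome build mm10 is named, per the submitters' processing notes. The aligner, the counting method, the annotation and any filter on cells are not given in the sources used here.

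The deposited tables used here hold 1 row per well with the plate, the position, the cell barcode, the sequencing batch, the number of cells the plate map lists (0 or 1), a total count and the number of genes detected. The total is a whole-number count made by the authors. Per the file headers it is named only as a total, so it is not known whether it counts reads or molecules or includes spike-in RNA. The number of genes is not corrected for depth. Gene-level counts, cell annotations and index-sort readouts were not analysed here, so no transcript, surface marker or cell type could be scored. The fixed rule for naming readouts and the fixed marker lists therefore named none.

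Of 120 listed plates, 118 were analysed: 33 plates of liver lymph node sorts from 1 table and 85 plates of the other sorts from a second table. A normal diet plate of lymph node doublets and a normal diet plate of liver CD45+ cells at week 2 were not analysed here. Plates were matched to labels by the amplification batch name in the sample title. All 118 plates listed 380 wells with 1 cell and 4 empty wells, 45312 wells in all, and no plate repeated the totals of another. The sequencing batch takes 12 values. Cells are not replicates. The plate is the replicate, and the plates' medians over the 380 cell wells were compared. The labels do not say whether plates came from separate animals, so the p-values measure the spread between plates, which may be technical.

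The planned tests had assumed fluorescence readouts. They were applied instead to the log2 of the plate median of genes and of the total, and to the share of cell wells with at least 100 genes and with at least 1000 genes. These thresholds, the comparison of weeks within a diet, and the comparison of diet effects between lymph node sorts were chosen after the tables had been seen. Diets, and sorts of the same tissue, were compared by a two-sided exact permutation test over plates. Labels were permuted within sequencing batch where at least 2 batches held both groups, and the difference was averaged over batches by their number of plates. Sorts were permuted within batch and diet. Where enumeration was too long, 100000 random relabellings were drawn. The difference between weeks or sorts in the effect of diet was tested with 100000 permutations of the diet labels. Benjamini-Hochberg adjustment covered the 2 readouts, or the 2 shares, of a comparison, and all 6 differences of a family of interactions. An adjusted p under 0.05 was a call. Standard errors use the variance between plates pooled within batches. Fold values are powers of 2 of the log2 difference.

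The plate median of the total ranged from 5979.5 to 64584, and the sum over a plate's cell wells from 2884885 to 48743533. With 380 wells, the 95% Wilson interval of a plate's share of wells had a half-width of at most 5.00 percentage points. A share of 0 allows up to 0.789%, from a limit of 3 counts. These limits cover counting error only. Thinning wells to 1 depth needs gene-level counts, so wells whose total lay between the 25th and 75th percentile of their sequencing batch were compared instead, as an alternative chosen after the data had been seen.

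The test was checked on simulated plates with the batches and the spread of real ones, 200 draws each. The lymph node T cells, the lymph node cDC and the liver CD45+ cells at week 2 were simulated. A 2-fold difference gave an unadjusted p under 0.05 in the exact permutation test in 100% of draws for each. With no difference, 4%, 2% and 5% of draws gave an unadjusted p under 0.05. Smaller differences and the other sorts were not simulated, so the check does not give the power for them. Alternatives were the mean of log2(value + 1) over wells, all listed wells, other handling of the batch, each plate left out in groups of 2 to 5, and pairs of plates with the same number. Untransformed medians, wells of middle depth, wells with at least 100 genes, wells without low-yield barcodes and share thresholds of 50, 200 and 500 genes were added later. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.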

Results

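Immune cells of mice on normal diet (ND) or a methionine and choline deficient diet (MCDD) were sorted from bone marrow, blood, liver and liver lymph nodes. The study's title concerns type 1 conventional dendritic cells (cDC1), which carry the receptor XCR1, in steatohepatitis. The sorts follow the dendritic cell lineage from marrow to liver and lymph node. They comprise common dendritic cell progenitors (CDP) and dendritic cell precursors (preDC) of the marrow, preDC of the liver, conventional dendritic cells (cDC) of blood, liver and lymph node, and lymph node T cells. Doublets of a T cell and a cDC, labelled PIC, were also sorted from the lymph nodes, and all CD45+ leukocytes from the liver at weeks 2, 4 and 8. There were 118 plates in 26 groups, each with 380 wells listed with a sorted cell or, in the PIC sort, a doublet. The liver CD45+ groups held 8 to 10 plates, the lymph node groups 3 to 7 plates, and the other 14 groups 2 plates each. The measurements are the genes detected and the total count of each well. They describe the yield of a well, not which genes its cell used. Neither is corrected for the sequencing depth of the plate, so a difference need not be a property of the cells.

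The empty wells gave the background. The 472 empty wells had a median of 17 genes and a total of 1666.5, against 345 genes and a total of 19596 in the 44840 cell wells. On liver CD45+ plates the empty wells had a median total of 5675.5, against 31710.5 in cell wells. In the other sorts these were 590 and 14229. On normal diet, the plate median averaged 101.5 ± 23.3 genes in blood cDC, 205.8 ± 54.1 in marrow CDP and 373.2 ± 15.2 in liver cDC (SD, n = 2 plates each). It averaged 513.5 ± 16.3 genes in liver preDC and 597 ± 259 in marrow preDC (SD, n = 2 plates each). Blood cDC had few genes at a plate median total of 14617.5 ± 442.6, which was above the 9404 ± 152.7 of liver cDC (SD, n = 2 plates each). The plate median total of the empty wells was also higher, at 2526 to 3061 on these blood plates against 135.5 to 681 on these liver plates. Blood cDC and marrow CDP were sequenced in 1 batch and the liver cDC, liver preDC and marrow preDC in another, so population and batch cannot be told apart between these sets.

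The liver CD45+ sort asks how the leukocytes of the liver changed over the course of the diet. Liver leukocytes at week 8 gave fewer genes per cell than at week 2, on both diets. On normal diet the plate median was 422.7 ± 92.7 genes at week 2 (SD, n = 9 plates) and 233.4 ± 68.7 at week 8 (SD, n = 10 plates). On MCDD it was 471.6 ± 77.3 genes at week 2 and 219.7 ± 51.1 at week 8 (SD, n = 10 plates each). Within the sequencing batches that held both weeks, week 8 was 1.73-fold lower on normal diet (log2 difference -0.79 ± 0.16 SE) and 2.06-fold lower on MCDD (-1.05 ± 0.13 SE). These batches held 6 plates of week 8 on each diet, and 5 plates of week 2 on normal diet and 6 on MCDD. Both differences gave an adjusted p of 0.00952 in the exact permutation test, from the smallest p it allows, 0.00476. The week 8 plates had the lower mean in both batches on both diets. In batch SB12 alone the log2 differences were -1.03 on normal diet and -0.89 on MCDD, and in batch SB16 alone -0.70 and -1.12. The total per well did not pass the same exact permutation test, with log2 differences of -0.34 ± 0.38 SE on normal diet (adjusted p = 0.310) and -0.53 ± 0.37 SE on MCDD (adjusted p = 0.214). Among wells of middle depth the differences in genes were -0.59 and -0.71.

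Week 4 lay between these values, at 372.9 ± 40.0 genes on normal diet (SD, n = 8 plates) and 392.5 ± 82.4 on MCDD (SD, n = 10 plates). Against week 2 within shared batches the log2 difference was -0.07 ± 0.10 SE on normal diet and -0.21 ± 0.20 SE on MCDD, with 4 plates of week 2 in these batches on each diet. Neither passed the exact permutation test (adjusted p = 0.571 and 0.422). Weeks 4 and 8 shared no sequencing batch, so a difference between them cannot be told apart from the batch.

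**Figure D1:**
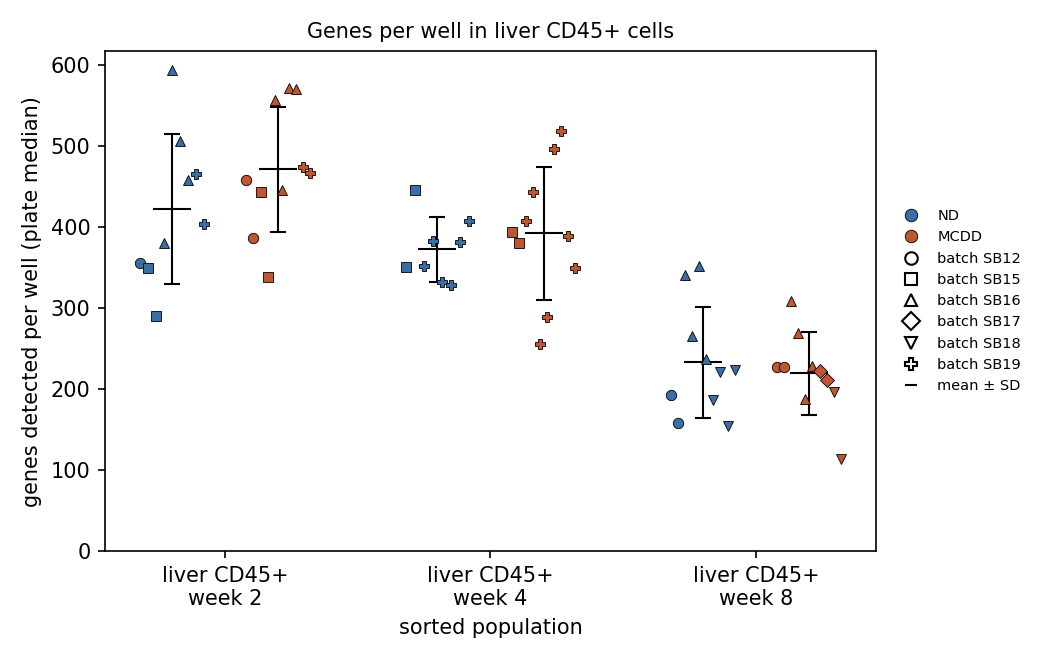
Genes detected per well in liver CD45+ cells, by week and diet. Each point is the median of the 380 cell wells of 1 plate, colours mark the diet, symbols the sequencing batch, and black bars the mean ± SD of plates. Week 8 averaged 233.4 genes on ND and 219.7 on MCDD, against 422.7 and 471.6 at week 2.

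Differences between diets in liver leukocytes were smaller than those between weeks 2 and 8. At week 2 MCDD plates had more genes per cell than normal diet plates in each of 4 batches, 1.14-fold overall (log2 difference 0.19 ± 0.10 SE). This gave an unadjusted p of 0.0446 and an adjusted p of 0.0892 in the exact permutation test, so it did not pass. The batches gave 0.24 in SB12, 0.28 in SB15, 0.16 in SB16 and 0.12 in SB19. The difference was 0.07 among wells of middle depth and 0.08 among wells with at least 100 genes. The share of cells with at least 100 genes was 92.0% ± 3.6 on MCDD (SD, n = 10 plates) and 87.3% ± 8.0 on normal diet (SD, n = 9 plates), with an adjusted p of 0.0635 in the exact permutation test. The share with at least 1000 genes lay the other way, at 11.2% ± 3.4 on MCDD and 13.7% ± 4.7 on normal diet (SD, n = 10 and 9 plates; exact permutation test, adjusted p = 0.12). This direction depended on the threshold and batch, since the difference of -2.31 percentage points within batches turned to 5.35 at 500 genes (exact permutation test, adjusted p = 0.0563) and to 1.18 in SB15. At week 4 the log2 difference in genes was 0.05 ± 0.13 SE and at week 8 -0.16 ± 0.14 SE, with adjusted p of 0.670 and 0.623 in permutation tests. The week 8 value was 0.38 in SB12, -0.27 in SB16 and -0.38 in SB18, and it turned to 0.11 among wells with at least 100 genes. The share with at least 100 genes at week 8 was 70.2% ± 7.7 on MCDD and 74.8% ± 6.3 on normal diet (SD, n = 10 plates each). The exact permutation test gave an adjusted p of 0.132, and the difference of -5.42 percentage points within batches turned to 3.03 in SB12. The tests at week 8 used 8 of the 10 MCDD plates, since batch SB17 held no normal diet plate. At week 4 it was 87.0% ± 6.2 on MCDD (n = 10 plates) and 88.9% ± 2.9 on normal diet (SD, n = 8 plates; permutation test, adjusted p = 0.458). The diet effect at week 8 minus that at week 2, planned without stratification by batch, was -0.24 on the log2 scale, with an adjusted p of 0.674 over 6 differences between weeks in a permutation test. Stratified by batch, as the effects above are, it was -0.35 (permutation test, adjusted p = 0.318).

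The lymph node sorts address contacts of T cells with dendritic cells. Doublets had 472.5 ± 245.4 genes on MCDD (SD, n = 5 plates) and 354.2 ± 170.6 on normal diet (SD, n = 3 plates). Single T cells had 351.8 ± 32.6 genes on MCDD and 393 ± 86.0 on normal diet (SD, n = 7 plates each). Single cDC had 409.3 ± 154.0 genes on MCDD (SD, n = 6 plates) and 345.6 ± 85.5 on normal diet (SD, n = 5 plates). Within batches the log2 difference between diets was 0.45 ± 0.10 SE for doublets, -0.16 ± 0.10 SE for T cells and -0.10 ± 0.13 SE for cDC. These values leave out batch SB399, which held MCDD plates alone, so 3, 6 and 5 MCDD plates entered them, against 3, 7 and 5 on normal diet. The MCDD doublet plates left out had 162 and 820.5 genes. Batch SB405 held 1 doublet plate per diet, so the SE for doublets comes from SB410 alone. It leaves out the spread between batches. Without stratification, over all doublet plates, their difference was 0.33 ± 0.59 SE. For doublets the exact permutation test gave p = 0.167, the smallest that their batches allow, and an adjusted p of 0.333. T cells and cDC did not pass either, with adjusted p of 0.210 and 0.5 in the exact permutation test. In batch SB405 alone the difference was 0.08 for doublets, -0.25 for T cells and 0.12 for cDC, and in SB410 alone it was 0.64, -0.05 and -0.32. Without stratification cDC turned to 0.18, and leaving out 1 of its 5 normal diet plates moved it between -0.14 and -0.03. The doublets' value was 0.71 with the mean over wells and 0.24 among wells with at least 100 genes. The diet effect in doublets exceeded that in T cells by 0.61 and that in cDC by 0.55 on the log2 scale. The adjusted p over 6 differences were 0.0774 and 0.133 in permutation tests, so neither passed. The share of lymph node cDC wells with at least 100 genes was 90.9% ± 7.2 on MCDD (SD, n = 6 plates) and 83.8% ± 7.1 on normal diet (SD, n = 5 plates; exact permutation test, adjusted p = 0.140). The difference of 6.07 percentage points within batches, from 5 plates per diet, fell to 1.25 at a threshold of 200 genes.

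**Figure D2:**
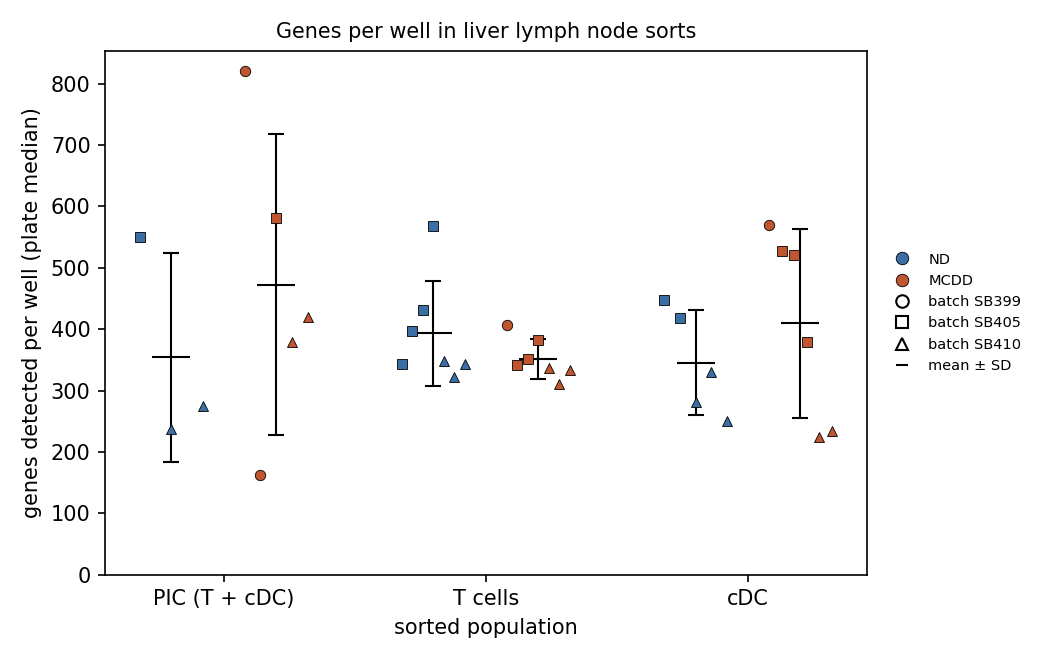
Genes detected per well in liver lymph node sorts, by diet. Each point is the median of the 380 cell wells of 1 plate, colours mark the diet, symbols the sequencing batch, and black bars the mean ± SD of plates. The 2 MCDD doublet plates of batch SB399 lie at 162 and 820.5 genes.

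Doublets hold 2 cells, so they were compared with each single-cell sort within batch and diet. The number of genes in doublets was 1.12-fold that in T cells (log2 difference 0.16 ± 0.24 SE) and 1.10-fold that in cDC (0.14 ± 0.28 SE). Neither differed in the permutation test (adjusted p = 0.551 and 0.684). Against T cells the difference was 0.45 among wells of middle depth (permutation test, adjusted p = 0.0780) and 0.32 among wells with at least 100 genes. T cells and cDC differed by 0.02 ± 0.08 SE on the log2 scale (permutation test, adjusted p = 0.838), and the batches disagreed, at -0.49 in SB399, -0.21 in SB405 and 0.36 in SB410. SB410 alone passed the exact permutation test (adjusted p = 0.0150), while among wells of middle depth T cells had fewer genes than cDC (-0.20 ± 0.07 SE; permutation test, adjusted p = 0.0350). Totals did differ. T cells had a higher total than doublets, which lay -0.44 ± 0.09 SE below them (permutation test, adjusted p = 0.0183), and than cDC (0.33 ± 0.11 SE, adjusted p = 0.0168). Batch SB410 gave most of these differences, at -0.96 for doublets against T cells and 0.59 for T cells against cDC. In SB405 they were -0.06 and 0.16, and in SB399, which held 1 T cell plate and 1 cDC plate, they were 0.15 and -0.09. Both calls were lost among wells with at least 100 genes, at -0.25 ± 0.15 SE and 0.22 ± 0.12 SE (adjusted p = 0.157 and 0.153 in permutation tests). The call of T cells against cDC was also lost without stratification, where the difference was no smaller but its error larger (0.37 ± 0.18 SE; permutation test, adjusted p = 0.0991), and that of doublets against T cells among wells of middle depth, which are chosen by their total (-0.10, adjusted p = 0.108). By diet, doublets lay at -0.65 against T cells on normal diet and at -0.27 on MCDD, and neither passed (permutation test, adjusted p = 0.0800 and 0.417).

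Marrow preDC showed the largest difference in genes between diets among the 13 comparisons by sort and week. They had 597 ± 259 genes on normal diet and 202 ± 68 on MCDD (SD, n = 2 plates each), a log2 difference of -1.54 ± 0.58 SE. The share of marrow preDC with at least 1000 genes was 27.9% ± 12.3 on normal diet and 3.2% ± 3.0 on MCDD (SD, n = 2 plates each), a difference of -24.7 percentage points that lay between -33.4 and -16.1 with 1 plate left out. The total did not go the same way, at 11123.5 ± 2546.3 on normal diet and 12959.5 ± 3043.4 on MCDD. The plate median total of the empty wells was 544 and 1283 on the MCDD plates, against 184.5 and 226 on normal diet. With 2 plates per diet, the difference in genes could not be called. Liver preDC, sorted with the same markers, had 513.5 ± 16.3 genes on normal diet and 518.5 ± 45.3 on MCDD (SD, n = 2 plates each), a log2 difference of 0.01 ± 0.09 SE. Marrow CDP had 205.8 ± 54.1 genes on normal diet and 175.8 ± 37.8 on MCDD (SD, n = 2 plates each).

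Among mature dendritic cells, 2 of the liver sorts had lower values on MCDD. Liver cDC of the Xcr1 reporter strain had 593.8 ± 81.0 genes on normal diet and 398.5 ± 99.0 on MCDD (SD, n = 2 plates each), a log2 difference of -0.59 ± 0.29 SE. Liver cDC under the stain labelled mDC had 545.5 ± 27.6 genes on normal diet and 424.5 ± 68.6 on MCDD (SD, n = 2 plates each), a log2 difference of -0.37 ± 0.17 SE. Their shares of cells with at least 1000 genes were 14.7% ± 7.1 against 6.1% ± 4.5 in the reporter strain and 14.6% ± 2.0 against 4.5% ± 1.9 under the mDC stain, normal diet first (SD, n = 2 plates each). The total in the reporter strain was also lower on MCDD, at 19354.8 ± 6599.8 against 28055.2 ± 13887.2 (SD, n = 2 plates each), and among wells of middle depth its difference in genes was -0.32. The liver cDC sort with no stain named gave the opposite sign, with 373.2 ± 15.2 genes on normal diet and 446.5 ± 63.6 on MCDD (SD, n = 2 plates each), a log2 difference of 0.25 ± 0.15 SE. It was sequenced in batch SB52, and the reporter strain and mDC stain sorts both in SB121. The contrast by stain or strain therefore cannot be told apart from the batch. Leaving out 1 plate moved the difference between -0.85 and -0.34 in the reporter strain, between -0.54 and -0.20 under the mDC stain and between 0.11 and 0.40 in the sort with no stain named. The reporter strain's difference in the share with at least 1000 genes lay between -13.7 and -3.7 percentage points. Blood cDC had 101.5 ± 23.3 and 94.5 ± 11.3 genes (SD, n = 2 plates each), and 0 of 380 wells on each blood plate reached 1000 genes, which allows a share of up to 0.789%. In all 7 sorts with 2 plates per diet the exact permutation test cannot go below p = 0.333, so none could be called.

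**Figure D3:**
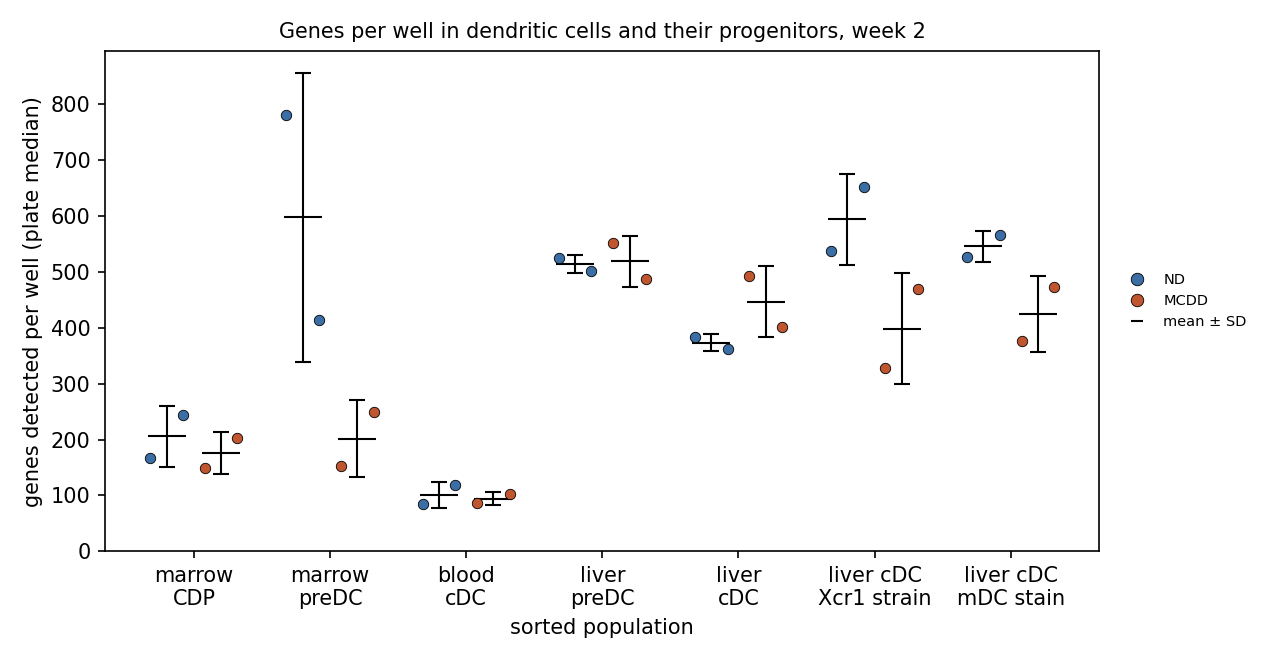
Genes detected per well in dendritic cells and their progenitors at week 2, by diet. Each point is the median of the 380 cell wells of 1 plate and black bars give the mean ± SD of 2 plates. Marrow preDC averaged 597 genes on ND and 202 on MCDD, while liver preDC averaged 513.5 and 518.5.

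Precursors were also compared with mature cells and across tissues. Liver preDC had 1.27-fold more genes than liver cDC (log2 difference 0.34 ± 0.09 SE, n = 4 plates each), higher on both diets. The adjusted p was 0.111 in the exact permutation test, whose smallest p is 0.0556. Liver preDC had 516 ± 27.9 genes and marrow preDC 399.4 ± 275.6 over both diets (SD, n = 4 plates each), a log2 difference of 0.63 ± 0.29 SE (exact permutation test, adjusted p = 0.444). By diet the sign differed, at -0.15 ± 0.46 SE on normal diet and 1.4 ± 0.36 SE on MCDD, so the pooled value describes neither diet, and leaving out 1 plate moved it between 0.37 and 0.93. Across all sorts and weeks, 0 of 13 diet comparisons of genes and 0 of 13 of totals passed the exact permutation test. An unadjusted p under 0.05 was reached by 1 comparison of genes and 0 of totals, and 5 of the 13 held enough plates to pass.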

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

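The corner tests below were set before their results were seen. On 2 plates the 4 wells listed as empty had more genes, by their median, than the cell wells. On the liver CD45+ plate of week 2 on normal diet numbered 2.2 the empty wells had a median of 643.5 genes, against 458 in its 380 cell wells. On the liver CD45+ plate of week 8 on MCDD numbered 1.3 the empty wells had 314.5 genes, against 196.5 in the cell wells. None of the 22 tests for a plate far from the others of its group, in genes or totals of groups of 5 to 10 plates, marked one, and no difference in diet effect between weeks or sorts passed its test.

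On the first plate the wells O2, P1 and P2 gave 649, 812 and 638 genes, and O1 gave 61. If the plate had been turned by 180 degrees, the wells A23, A24, B23 and B24 would be the empty ones, and their median was 27.5 genes. If it had been flipped top to bottom, the wells A1, A2, B1 and B2 would be empty, and their median was 31 genes, while the remaining corner had 418.5. Both are at background, so a plate or plate map in another orientation may account for the pattern, but at most 1 of these orientations can hold and neither explains both corners. A median under 100 genes occurred at the first of these corners on 7 of 118 plates, at the second on 8, and at both on this plate alone. No biological explanation was tested.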

How the results depend on the processing

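Untransformed medians, middle depth, wells with at least 100 genes, low-yield barcode removal and other share thresholds were chosen after seeing the data. So were correlations of same-numbered plates and settings of lymph node interactions. The 41 results tested individually in the text had 393 alternatives. Of these, 341 kept direction and side of the threshold, 38 turned (1 past the threshold), 12 lost a call and 2 gained one. Tests with no p under 0.05 possible, as with 2 plates per diet, could gain no call and could only lose one. All main values that turned were uncalled, except totals in batch SB399 alone. Causes were not tested, but single batches hold fewer plates.

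Week 8 against 2 in genes kept direction in all settings. It lost its call in single batches, at -0.89 on MCDD and -1.03 on normal diet in SB12 and at -1.12 and -0.70 in SB16. Among the log2 differences by diet, lymph node cDC turned to 0.16 with the mean over wells, 0.18 without stratification and 0.12 in SB405. Week 4 turned to -0.034 with the mean and -0.032 in SB15. Week 8 turned to 0.38 in SB12 and 0.11 with at least 100 genes. Blood cDC turned to 0.047 at middle depth and 0.13 with at least 100 genes, and liver preDC to -0.014 with the mean and -0.17 at middle depth. Leaving out 1 plate gave -0.49 to 0.052 for marrow CDP, -0.33 to 0.15 for blood cDC and -0.078 to 0.10 for liver preDC. The diet effect at week 4 minus week 2 turned to 0.11 at middle depth. Week 4 against 2 on normal diet turned to 0.31 in SB15. The 1000-gene share at week 2 turned to 1.18 points in SB15 and 5.35 at 500 genes. The 100-gene share turned to -0.92 points at week 2 in SB19 and 3.03 at week 8 in SB12.

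Among sorts, genes of doublets against T cells turned to -0.019 with the mean, -0.16 in SB399 and -0.055 in SB410, and against cDC to -0.65 in SB399. Genes of T cells against cDC turned to -0.49 in SB399, -0.21 in SB405, -0.025 untransformed, -0.20 at middle depth (permutation test, adjusted p = 0.0350) and -0.095 with at least 100 genes, and gained a call in SB410 at 0.36 (adjusted p = 0.0150). Totals turned in SB399 for doublets against T cells (0.15) and cDC (0.054, and 0.12 in SB405) and for T cells against cDC (-0.093). Those of week 8 against 2 on MCDD turned to 0.10 in SB12.

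Pairing plates by label number, as a replicate block, raised the diet difference in genes at week 2 to 0.26 (exact sign-flip permutation test, adjusted p = 0.0312; 0.0312 to 1 over its alternatives). MCDD was higher in 7 of 7 pairs. The block turned genes of T cells against cDC to -0.12. Totals were 0.19 for T cells against cDC (adjusted p = 0.562). For doublets against T cells they were -0.54, where 4 pairs allow no call (smallest p 0.125). The block changed no other call. The labels do not say that a number marks a shared animal. Between same-numbered plates, deviations of the log2 genes from the group mean had r = 0.78, -0.77 and 0.53 at weeks 2, 4 and 8 (7, 6 and 10 pairs; rho = 0.79, -0.94 and 0.41; permutation test, adjusted p of r = 0.110, 0.110 and 0.116, of rho = 0.0721, 0.0516 and 0.242). Without the 2 farthest pairs r was 0.73, -0.80 and 0.67. From the batch mean, r was 0.24, -0.67 and 0.17 (rho = 0.39, -0.77 and 0.19; permutation test, adjusted p from 0.310 to 0.636). The sign changed between weeks, so no pairing was assumed. Other readout scales, scatter trimming, detector gain, marker thresholds, annotated types and cells per plate were not run.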

Other observations

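The tests of the sequencing batch and of the plate position below were written after their results had been seen. Listed cell wells were at background in the same places on many plates. In the 85 plates outside the lymph node, the wells D9 and E10 had under 100 genes on 85 of 85 plates each, with medians of 11 and 16 genes. Their mean ranks among the 380 cell wells of their plates were 1.54% and 1.84%. The lymph node plates assign barcodes to wells differently, with 192 of 384 wells sharing a barcode. There the 2 barcodes had mean ranks of 45.925% and 45.96%, which argues against the barcode sequence as the source at these 2 wells. The wells D9 and E10 had 52.02% and 48.999% there, which argues against the position by itself. Other low-yield barcodes were not set against these explanations. A fault tied to the batch of plates or primers used for the 85 plates stays open and was not tested. Cells never sorted into these wells would leave the total of an empty well. Over the 85 plates the median total was 767 in D9 and 123 in E10. On the 57 liver CD45+ plates, most of the 85, the empty wells' plate median was never below 804. On some of those plates both wells thus lay below any of these medians, which argues against a missing cell as the only source there. The other plates were not compared singly.

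The lower number of genes in liver leukocytes at week 8 than at week 2 was set against 3 technical explanations. Within shared sequencing batches the log2 difference was -0.7881 ± 0.16 SE on normal diet and -1.05 ± 0.13 SE on MCDD, so the sequencing batch is not the whole cause. Among wells of middle depth it was -0.5873 ± 0.21 SE on normal diet and -0.71 ± 0.15 SE on MCDD. Among wells with at least 100 genes it was -0.6589 ± 0.15 SE and -0.62 ± 0.12 SE. The difference was smaller in both sets of wells, so a lower total or more wells without usable RNA may account for part of it. Neither set can show whether they account for all of it. The band of middle depth is wide, and the total may include spike-in RNA. The cut at 100 genes is made on the gene number itself, and wells above it may still hold little RNA. A different makeup of the CD45+ cells, the time on the diet, the age of the mice and the sort or library day stay open, since no cell types or days were analysed here.

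The empty well O2 carried high totals on liver CD45+ plates. Its median total was 44676, against 4107 in the other 3 empty wells, and it exceeded the plate's cell median on 34 of 57 plates. In the other sorts the medians were 571 and 592, and it exceeded the cell median on 0 of 61 plates. On the MCDD plate of week 2 numbered 2.6 it had a total of 7085849 and 1167 genes. In all, 26 of the 472 empty wells had at least 100 genes, 24 of them on liver CD45+ plates.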
